A study of Saccharomyces cerevisiae with 43 samples.

How the data were processed

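Contacts between parts of the yeast genome were measured in 43 samples that fall into 15 groups. Carbon-copy chromosome conformation capture (5C) covered chromosomes III, V and XII in 39 of them, 33 of strain SK1 (11 groups of 3) and 6 of strain W303 (2 groups of 3). Hi-C covered the whole genome in 4 SK1 samples (2 groups of 2). Per the labels, replicates are biological, SK1 cells grew without uracil and W303 cells in YPAD at 30 °C, and cells were fixed in 3% formaldehyde for 20 min. Chromatin was digested with HindIII. The W303 strains carry arrays of bacterial operator sites near HML, MAT and HMR.

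The authors aligned reads with Novoalign, whose version is not given in the sources used here. The deposited 5C values are log2 ratios of the balanced matrix of 1 library, in bins of 10 kb, to an expected value that the files do not describe. Library medians of these log2 values lay between -0.16 and -0.03, and medians were near 0 at every separation, so the decay of contact with distance had already been divided out. The authors placed probes designed on an older S288C assembly onto the SK1 assembly (sk1_MvO_V1) and onto a W303 assembly, and kept the part of XII beyond the ribosomal DNA as a separate chromosome. The deposited Hi-C values are balanced signal, scaled so that each library's matrix of 1193 bins sums to 100000000. Neither kind of file holds read counts, so the depth per sample is unknown and no counting interval can be given. Other steps upstream of the matrices are not given in the sources used here.

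Each unordered pair of bins was used once. A pair was tested in 5C when all libraries of the fit had a value, which left 8426 of 18915 pairs in SK1 and 16571 of 19701 in W303. In Hi-C, log2 was taken of pairs within a chromosome that were above 0 in all 4 libraries (47218 pairs). Each library was centred on its median over the tested pairs. Of the tested SK1 5C pairs, 304 lie within III, 2971 within V or XII, 1701 join III to another chromosome, and 3450 join others.

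Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), with the package data.table (version 1.17.8) for input and output. The 33 SK1 5C samples were fitted together with 1 mean per group (22 residual degrees of freedom), and the W303 (4) and Hi-C (2) samples separately. The estimated prior degrees of freedom were 3.18, 3.43 and 1.74. Adjusted p-values are Benjamini-Hochberg, over all tested pairs within a comparison, and a pair or block was called at an adjusted p under 0.05. There were 20 comparisons within SK1 5C, including 4 tests of whether the effect of a deletion differs between MATa and MATalpha (interactions). Many of these comparisons share the MATa or MATalpha libraries, so they are not independent. All tests are two-sided.

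Chromosome III was divided at its landmarks into 7 parts, and values were averaged per library over each block, meaning all tested pairs that join a given pair of parts. Further blocks join III, its left end or its centromere to V and XII, and control blocks hold the pairs within V or within XII, either all of them or those of the left telomere region (40 kb) with the rest of the chromosome. The matrix of 37 blocks in SK1 was fitted with limma as above, with adjustment over the blocks of a comparison. Group means are given with the SD over libraries, and differences with the limma standard error (SE). Contrasts of several blocks or of several comparisons, in the closing section only, carry an SE from the variance between libraries within groups. Exact permutation tests of the library means were run beside limma; 3 libraries against 3 cannot give a p under 0.1, and 2 against 2 cannot give one under 0.333. In Hi-C the prior degrees of freedom of the block fit were infinite, so all blocks share 1 SE and these p-values rest on that pooled spread. Sets of pairs per block were also tested with fry (limma).

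The 5 landmarks (HML, RE, CEN3, MAT and HMR) were placed by finding the design fragment that holds each locus, using the order of genes in the RefSeq table of S288C assembly R64 for names and neighbours, and reading that fragment's position in the deposited probe tables. RE was taken as the interval between KAR4 and SPB1. In all 3 data sets the bin placed at CEN3 was the bin of III with most contact to the CEN5 region. In SK1 the RE bin (10001 to 20000) holds 1 probe fragment, and the labels do not say how far the RE deletions reach into it.

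Sites named in the text follow a rule fixed before the data were examined, as were the blocks, the comparisons and their limma tests, and the alternatives other than the 2 listed below. Some tests of explanations were chosen only after results were seen, and are named where they are reported. The rule takes the 10 landmark pairs, of which 8 could be tested in SK1 5C. For MATa against MATalpha in SK1 it adds the 10 called pairs within III with the largest rise and the 10 with the largest fall, among those whose libraries do not overlap between groups. For every other comparison it adds the 3 with the largest rise and fall, and for each comparison the 3 bins of III in most called pairs. For those other comparisons the text prints only part of the sites that the rule picks. A slope of log2 value against log10 of distance from 20 to 200 kb was computed per library and chromosome.

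Replicate numbers were checked for pairing by correlating deviations from the group mean between libraries of the same number. In W303, 3 of 3 correlations were above 0.1 (0.105 to 0.336), so W303 results were also fitted with the replicate number as a block.

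The alternatives chosen beforehand were the replicate block, no centring, centring per distance, fitting only the groups compared, leaving out pairs under 30 kb, accepting pairs finite in at least 2 libraries of each group, and leaving out each library in turn. For Hi-C a pseudocount (the 10% quantile), leaving out the lowest 25% of pairs, and leaving out pairs under 30 kb were chosen beforehand. Library weights (arrayWeights) and leaving out the RE bin were added after the data had been seen.

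The code was tested on simulated data made from the same libraries. Of changes of 1 and 2 (log2) added to 100 pairs each, 30% and 73% were recovered in SK1 5C, with 8 false calls among 111. In W303 the shares were 3% and 61%, with 2 false calls among 66, and in Hi-C 0% and 0%. A block raised by 0.5 was estimated at 0.56 in SK1 and 0.50 in W303, and called in both. Of the blocks unchanged in the simulation, 1 was falsely called in SK1 (37 blocks tested) and 0 in W303 (38). The simulated noise was drawn for each pair on its own, so it lacks spread that a library shares across the pairs of a block. The block result therefore does not give the power for blocks in the real data.

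The deposited Hi-C matrices that hold log2 ratios or differences of replicates, or pooled replicates, were not used here, since the matrices of single libraries were. The lists of significant differences that the labels name were not used here. A line of the probe table was empty in the copy used and was left out. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the figures.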

Results

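Contacts along the chromosomes of Saccharomyces cerevisiae were measured in haploid cells of mating type MATa or MATalpha and in a diploid. The MAT locus on chromosome III sets the mating type, and silent copies of its information lie at HML near the left end of III and at HMR near the right end. The recombination enhancer (RE), a region of the left arm, governs which silent copy a MATa cell uses when MAT is broken and repaired. Fkh1 is a forkhead protein that binds RE. 5C reads ligation products between chosen restriction fragments, and was applied to 33 SK1 libraries in 11 groups of 3: MATa, MATalpha, diploid, and each haploid with deltaRE_left, deltaRE_right, deltaRE_whole or deltaFkh1. The labels do not give the ends of the RE deletions. A further 6 5C libraries came from W303 (3 MATa, 3 MATalpha), and 4 Hi-C libraries, which read ligation products genome-wide, from SK1 (2 MATa, 2 MATalpha).

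Read counts were not used here, so the depth behind each value is unknown. Missing values took 21.8 to 44.6% of the pairs of bins in the SK1 5C libraries, most in MATalpha replicate 1, and 14.6 to 15.0% in W303. Pairs at 0 within chromosomes took 0.0683 to 4.51% in the Hi-C libraries, most in MATalpha replicate 1. Across pairs of bins, which are not independent, replicates of a group correlated with r between 0.454 and 0.889 in SK1 5C and between 0.584 and 0.759 in W303, and with r of 0.950 (MATalpha) and 0.987 (MATa) in Hi-C. Values below are log2 ratios of observed to expected contact for 5C and log2 balanced signal for Hi-C, given as mean ± SD over the 3 (5C) or 2 (Hi-C) libraries of a group.

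Positions on III are those of the SK1 assembly unless W303 is named. The 7 parts of III are the left end (1 to 30000, with HML and RE), the left middle (30001 to 70000), the centromere part (70001 to 120000), the right proximal part (120001 to 170000), the MAT part (170001 to 220000), the right distal part (220001 to 260000) and the right end (260001 to 313017, with HMR). A block is the set of tested pairs of bins that join a given pair of parts. In SK1 5C, 9 of 18 pairs of the left end with the right end were tested, and 3 of 15 within the right end. The right end is therefore covered only in part. In each called 5C block given below with its difference, the libraries of a group all lay on the same side of those of the other group, except where overlap is stated.

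The first comparison asked whether the conformation of III differs between the mating types. In MATa the left end of III made more contact with the middle of the chromosome than in MATalpha. Left end with the centromere part was 0.20 ± 0.06 in MATa and -1.22 ± 0.30 in MATalpha (n = 3 each), a rise of 1.42 (SE 0.123, limma adjusted p 1.78e-10). With the right proximal part the left end was at 0.87 ± 0.07 against -0.14 ± 0.10 (rise 1.02, SE 0.0669, adjusted p 7.35e-13). Smaller rises joined the left end to the MAT part (0.65, SE 0.120, adjusted p 4.93e-05) and to the left middle (0.54, SE 0.0586, adjusted p 1.25e-08). In these 4 blocks the 3 MATa libraries all lay above the 3 MATalpha libraries, and the exact permutation p was 0.1, the smallest that 3 against 3 can give.

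The right end of III also made more contact with the middle of the chromosome in MATa. Right end with the centromere part was -0.70 ± 0.08 in MATa and -1.53 ± 0.25 in MATalpha (rise 0.84, SE 0.146, adjusted p 3.05e-05), and with the right proximal part 0.08 ± 0.06 against -0.48 ± 0.18 (rise 0.56, SE 0.0873, adjusted p 6.52e-06). The left middle rose with the centromere part by 0.41, with the right proximal part by 0.41 and with the MAT part by 0.36 (adjusted p 0.00089, 4.93e-05 and 0.00316), and the centromere part rose with the right proximal part by 0.31 (adjusted p 0.00713). In all, 16 of 28 blocks within III were called, all higher in MATa, by 0.15 to 1.42. Left end with right end was 2.39 ± 0.29 in MATa and 2.35 ± 0.57 in MATalpha and was not called (difference 0.04, SE 0.255, adjusted p 0.891).

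Some smaller rises rested on a library. Left middle with itself rose by 0.34, but by 0.05, and was not called, without MATalpha replicate 1. Left middle with the right end rose by 0.52 with overlapping libraries, but was not called without MATalpha replicate 2 (0.35) or MATa replicate 1 (0.35). Right proximal with right distal rose by 0.27, but was not called without MATalpha replicate 3 (0.24) or MATa replicate 1 (0.23). Centromere with right distal rose by 0.31 with overlapping libraries, but was not called without MATalpha replicate 2 (0.17), MATalpha replicate 3 (0.29), MATa replicate 1 (0.27) or MATa replicate 2 (0.30). Right proximal with MAT rose by 0.15 and was not called without MATalpha replicate 2 (0.15) or 3 (0.12), or MATa replicate 1 (0.15) or 3 (0.13). Centromere with MAT rose by 0.30 with overlapping libraries and was not called when only the 2 groups were fitted.

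Between chromosomes, the left end of III in MATa was lower with the telomere regions of V and XII and higher with their centromere regions. With the telomeres it was 1.85 ± 0.06 in MATa and 2.63 ± 0.10 in MATalpha (difference -0.78, SE 0.143, adjusted p 4.93e-05). With CEN5 and CEN12 it was 0.90 ± 0.10 against 0.36 ± 0.23 (difference 0.54, SE 0.0831, adjusted p 5.93e-06). None of the 4 control blocks within V and XII was called by limma (0 at adjusted p under 0.05). III as a whole with XII fell by 0.15, but was not called without MATalpha replicate 3 (-0.11) or MATa replicate 3 (-0.12), without centring (-0.08), centred per distance (-0.05) or when only the 2 groups were fitted (-0.17).

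**Figure D1:**
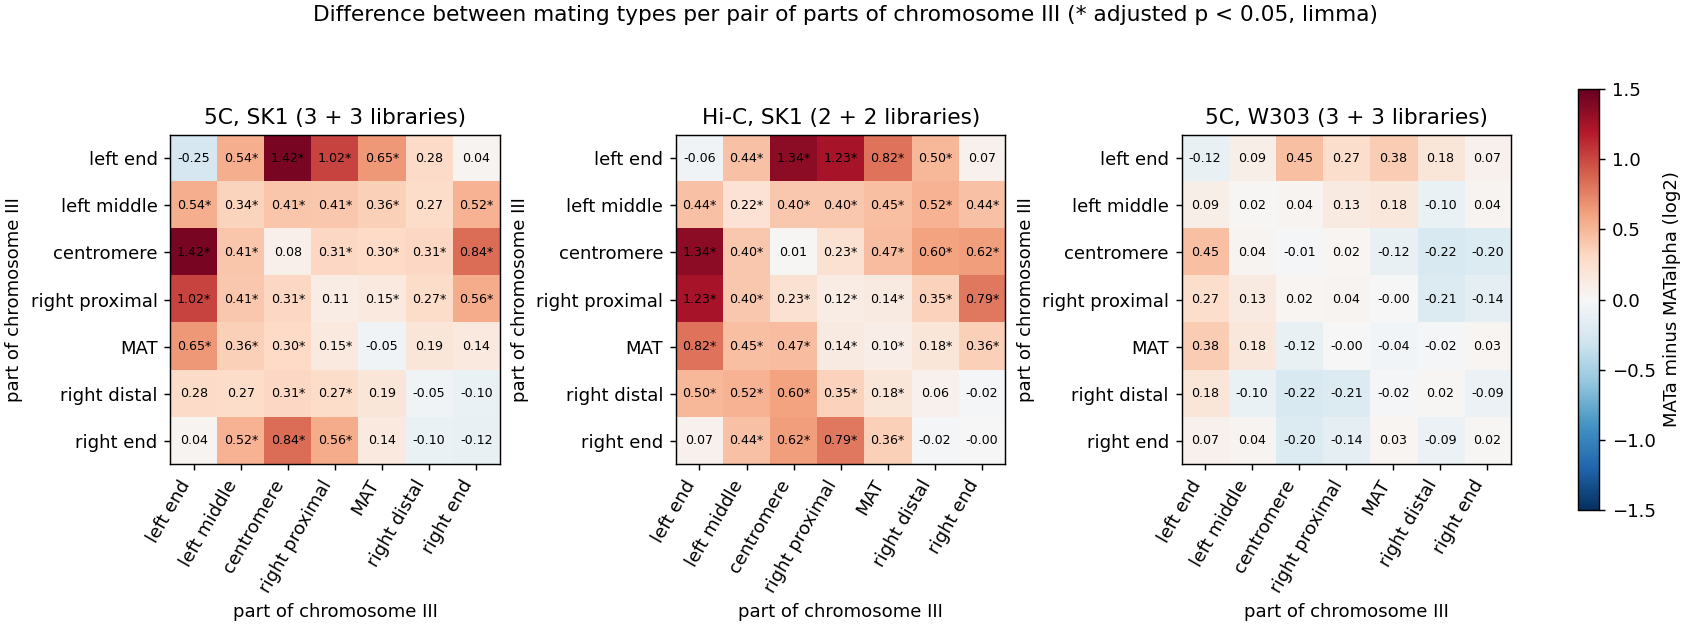
MATa minus MATalpha log2 difference for each pair of parts of III, in SK1 5C (3 libraries per group), SK1 Hi-C (2 per group) and W303 5C (3 per group); colour gives the difference and an asterisk an adjusted p under 0.05. In SK1 the left end with the centromere part differed by 1.42 in 5C and 1.34 in Hi-C, and no W303 block was called in the fit shown, without the replicate block (5 with it).

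At the level of pairs of 10 kb bins, 40 of 8426 pairs were called between MATa and MATalpha, 36 higher in MATa. Of them 21 were among the 304 pairs within III (6.91%), against 0.0977% of pairs within V and 0.308% within XII. All 21 were higher in MATa, with the 3 libraries of each group apart; over all pairs 12.1% were apart, where chance gives 10%. The mean absolute difference was 0.449 on III, 0.284 on V and 0.286 on XII. This count of 40 fell to 20 without MATa replicate 1 and to 25 without MATa replicate 3, rose to 61 without MATalpha replicate 3, and was 0 when only the 2 groups were fitted.

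The bin at 1 to 10000, which holds HML, took part in 7 of the 21 called pairs within III, and the bins at 120001 to 130000 and 20001 to 30000 in 6 and 5. The pair of bins 20001 to 30000 and 80001 to 90000 rose by 1.62 (SE 0.209, adjusted p 0.00026), from -1.33 ± 0.47 to 0.29 ± 0.09. Bins 1 to 10000 and 120001 to 130000 rose by 1.85 (SE 0.289, adjusted p 0.00174), and bins 20001 to 30000 and 110001 to 120000 by 1.29 (SE 0.171, adjusted p 0.00026). These 3 pairs were called without any 1 library. The other 7 of the 10 named pairs joined the left end to the centromere or right proximal part, rose by 1.32 to 1.89, and were each not called without at least 1 library. These libraries were MATalpha replicate 1 (for 1 to 10000 with 80001 to 90000, 1.72, and 10001 to 20000 with 110001 to 120000, 1.14), MATalpha replicate 2 (for 1 to 10000 with 80001 to 90000, 1.59, 70001 to 80000, 1.39, 100001 to 110000, 1.16, and 140001 to 150000, 1.00), MATa replicate 1 (for 1 to 10000 with 80001 to 90000, 1.70, 70001 to 80000, 1.51, and 140001 to 150000, 1.31, and for 20001 to 30000 with 70001 to 80000, 1.14), MATa replicate 2 (for 1 to 10000 with 80001 to 90000, 1.93) and MATa replicate 3 (for 1 to 10000 with 100001 to 110000, 1.29, and 10001 to 20000 with 120001 to 130000, 1.49).

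Among the 8 landmark pairs that could be tested, limma called 0 over all pairs of bins and 3 when adjusted over the list alone. HML with MAT was 0.83 ± 0.09 in MATa and -0.60 ± 0.69 in MATalpha (difference 1.43, SE 0.457, adjusted p over the list 0.0174, unadjusted p 0.00435). HML with CEN3 was higher by 0.94 (SE 0.268, list p 0.0136) and CEN3 with HMR by 1.00 (SE 0.381, list p 0.0378). HML with HMR was 3.88 ± 0.72 in MATa and 3.55 ± 1.60 in MATalpha, not called, and its difference of 0.33 ranged from -0.59 (without MATalpha replicate 2) to 0.89 (without MATalpha replicate 1). RE with HMR was 4.15 ± 0.38 against 3.91 ± 0.56 and was not called. HML, MAT and HMR share sequence, and how reads from shared sequence were assigned is not given in the sources used here.

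The slope of 5C value against log10 distance on III was 0.15 ± 0.11 in MATa and -0.17 ± 0.12 in MATalpha (difference 0.32, exact permutation p 0.1, n = 3 each), and at 30 to 150 kb the difference was 0.56. On V and XII the 5C slopes differed by -0.04 and -0.01 (exact permutation p 0.7 and 0.9, n = 3 each).

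Hi-C asked whether III stands out when every chromosome is measured in the same strains. Within III, left end with the centromere part was 2.77 ± 0.01 in MATa and 1.43 ± 0.04 in MATalpha (n = 2 each; rise 1.34, SE 0.0439). With the right proximal part the left end rose by 1.23 (2.36 ± 0.03 against 1.13 ± 0.06) and with the MAT part by 0.82 (2.07 ± 0.03 against 1.25 ± 0.06). Right end rose with the right proximal part by 0.79 and with the centromere part by 0.62. Of 28 blocks within III, 22 were called by limma, all higher in MATa by 0.10 to 1.34, and left end with right end was not (2.35 ± 0.01 against 2.28 ± 0.01, difference 0.07). The exact permutation test of 2 against 2 cannot give a p under 0.333, and the block p-values rest on a spread pooled over all blocks; 2 control blocks were called too, at 0.15 each. The one of V was not called without MATa replicate 2 (0.13), and the one of XII not without MATalpha replicate 2 (0.12) or MATa replicate 1 (0.08) or centred per distance (0.09). With the lowest 25% of pairs left out, the one of XII was 0.31 and called. The Hi-C values keep the decay with distance, and its slope was shallower in MATa on III, V and XII. The differences were 0.59, 0.20 and 0.12 (exact permutation p 0.333 each, n = 2 each), so V and XII shifted too. Of the 22 blocks called within III, 19 kept their call in every alternative run, centring per distance among them.

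The mean absolute MATa minus MATalpha difference in Hi-C was 0.460 on III, 2.93 times the larger of the 2 other ways to divide the 4 libraries. On the other chromosomes it was 0.157 to 0.335, or 1.01 to 1.70 times the larger other division. For pairs of bins limma called 0 of 47218, and at an unadjusted p under 0.05 there were 3177, of which 155 were among the 461 pairs on III (33.6%, against at most 8.45% on another chromosome). The simulation recovered no changes per pair at this size. Blocks of the right proximal part with itself (0.12) or with MAT (0.14) and of MAT with itself (0.10) were not called when libraries were left out: the first without MATalpha replicate 1 (0.07) or MATa replicate 1 (0.12) or 2 (0.11), the next without MATa replicate 1 (0.13) or 2 (0.14), and the last without MATalpha replicate 1 (0.06) or MATa replicate 1 (0.08) or 2 (0.13).

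**Figure D2:**
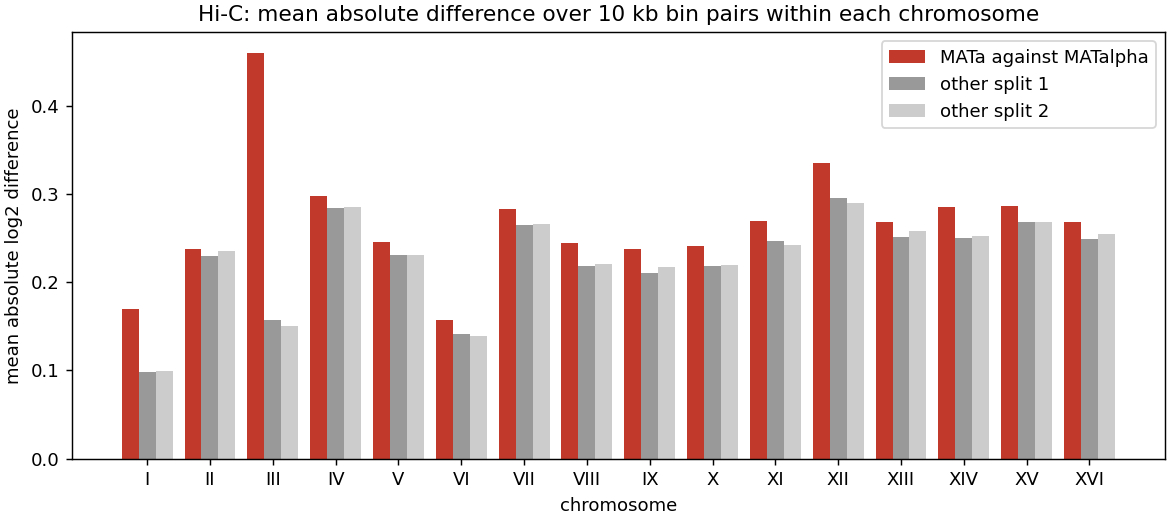
Mean absolute log2 difference in Hi-C per chromosome for MATa against MATalpha (2 libraries each) and for the 2 other ways to divide the 4 libraries. On III the difference between mating types is 0.460, and the larger of the other divisions gives 0.157.

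Landmark pairs in Hi-C gave 4 calls of 10 when adjusted over the list alone and 0 over all pairs (limma). RE with CEN3 was higher in MATa by 1.78 (SE 0.253, list p 0.0139, unadjusted p 0.00278), HML with CEN3 by 1.10 (SE 0.136, list p 0.0139), MAT with HMR by 1.13 (SE 0.238, list p 0.0271) and CEN3 with HMR by 1.07 (SE 0.227, list p 0.0271). HML with MAT was 2.97 ± 0.35 in MATa and 3.70 ± 0.07 in MATalpha, a difference of -0.74 (SE 0.222, list p 0.0656) opposite in sign to that in 5C. The shared sequence of HML, MAT and HMR limits these Hi-C pairs too. Differences of MAT with HMR and with HML may reflect how such reads were assigned, which was not tested.

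The W303 libraries asked the same question in another strain. Left end with the centromere part was 0.16 ± 0.13 in MATa and -0.29 ± 0.06 in MATalpha (n = 3 each), a difference of 0.45 (SE 0.0762, limma adjusted p 0.0549) that did not pass. Left end with MAT differed by 0.38 (SE 0.0955, adjusted p 0.170) and with the right proximal part by 0.27 (SE 0.0821, adjusted p 0.244); the 3 MATa libraries lay above the 3 MATalpha libraries in each block (exact permutation p 0.1). With the replicate number as a block, 5 blocks passed, among them left end with the centromere part (SE 0.0432, adjusted p 0.00286), MAT (adjusted p 0.00286) and the right proximal part (adjusted p 0.00809). That fit leaves fewer residual degrees of freedom than the 4 of the fit without it, and the pairing was read from the same 6 libraries. Limma called 0 of 38 blocks and 0 of 16571 pairs without the replicate block, and 536 pairs had an unadjusted p under 0.05. Left end with the centromere part passed also when centred per distance (0.44, and with MAT 0.40), without MATa replicate 1 (0.52) and with library weights (0.45), and over all ways of fitting it its adjusted p ranged from 0.00286 to 0.292 (with MAT, to 0.564). Adjusted over the list alone, RE with CEN3 (1.39, SE 0.305, list p 0.0226) and RE with MAT (0.95, SE 0.263, list p 0.0383) passed. HML with HMR was 0.40 ± 0.36 in MATa and -0.16 ± 0.63 in MATalpha and was not called.

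The diploid was compared with each haploid to place it between the mating types. These comparisons, and those with wild type below, reuse the same MATa and MATalpha libraries and are not independent. Left end with the centromere part was 0.02 ± 0.06 in the diploid (n = 3), higher than in MATalpha by 1.24 (SE 0.123, adjusted p 3.2e-09) and lower than in MATa by 0.18, which was not called (difference -0.18, adjusted p 0.651). Its left end with the right proximal part was at 0.68 ± 0.11, higher than in MATalpha by 0.82 (SE 0.0669, adjusted p 9.63e-11), and with the MAT part 1.03 ± 0.13, higher by 0.68 (adjusted p 4.43e-05). Against MATalpha, 16 of 28 blocks within III were called, 15 of them higher in the diploid, and right end with the centromere part rose by 0.68 (SE 0.146, adjusted p 0.000427). Of the 16, 8 kept their call in every alternative run. The other 8 lost it when only the 2 groups were fitted, and 7 of them without a library; libraries overlapped in left end with itself and with right distal, left middle with right end, and centromere with right distal. The 7 were left end with itself (-0.42; -0.24 without MATalpha replicate 1, -0.33 without diploid replicate 1) and with right distal (0.43; 0.30 without MATalpha replicate 2, 0.34 without diploid replicate 2). Left middle lost it with itself (0.25; 0.07 without MATalpha replicate 1, 0.14 without diploid replicate 1), with MAT (0.29; 0.20 without MATalpha replicate 2, 0.26 without diploid replicate 1) and with the right end (0.49; 0.32 and 0.38 without the same libraries). The centromere part lost it with MAT (0.24; 0.20 and 0.21 without MATalpha replicates 2 and 3, 0.19 without diploid replicate 1) and with right distal (0.38; 0.23, 0.35 and 0.28 without the same libraries). Against MATa, limma called 0 of 37 blocks. The slope of 5C value against log10 distance on III placed the diploid outside both haploids. It was 0.42 ± 0.03 in the diploid, 0.15 ± 0.11 in MATa and -0.17 ± 0.12 in MATalpha. The exact permutation p was 0.1 against each (n = 3 each), the smallest that 3 against 3 can give.

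For pairs of bins, 12 were called between diploid and MATalpha (7 of them within III, all higher in the diploid) and 1 between diploid and MATa, a fall between chromosomes other than III. At an unadjusted p under 0.05 there were 760 and 598. The count of 12 became 21, 34 and 34 without MATalpha replicates 1, 2 and 3, and 0 when only the 2 groups were fitted. The count of 1 became 0 without MATa replicate 1, 6 without MATa replicate 2, 2 without diploid replicate 1 and 11 without diploid replicate 3. Bins 10001 to 20000 and 110001 to 120000 showed the largest named rise over MATalpha (1.67, SE 0.240, adjusted p 0.000452).

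Strains with RE deletions asked whether the difference between mating types needs RE. In deltaRE_right cells, left end with the centromere part was -0.58 ± 0.06 in MATa and -0.68 ± 0.13 in MATalpha (n = 3 each; difference 0.10, SE 0.123, adjusted p 0.782), and with the right proximal part 0.25 ± 0.05 and 0.30 ± 0.02 (difference -0.06, SE 0.0669, adjusted p 0.782). In deltaRE_whole cells, left end with the centromere part was -0.56 ± 0.06 in MATa and -0.47 ± 0.04 in MATalpha (difference -0.09, SE 0.123, adjusted p 0.749). Limma called 0 of 37 blocks in deltaRE_right and 1 in deltaRE_whole, left end with the right proximal part (0.41 ± 0.02 against 0.15 ± 0.01; rise 0.26, SE 0.0669, adjusted p 0.0195). That call was lost without any 1 of its 6 libraries, with values of 0.25 to 0.28.

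The loss of the mating type difference was itself tested as an interaction. The MATa minus MATalpha difference at left end with the centromere part was smaller in deltaRE_right than in wild type by 1.32 (interaction -1.32, SE 0.174, adjusted p 8.4e-07) and smaller in deltaRE_whole by 1.52 (interaction -1.52, SE 0.174, adjusted p 1.29e-07). At left end with the right proximal part the interactions were -1.08 (SE 0.0947, adjusted p 5.42e-10) and -0.75 (SE 0.0947, adjusted p 3.7e-07). These 4 calls held in every alternative run. Right end with the centromere part and with the right proximal part also lost their difference (-0.81 and -0.60 in deltaRE_right, -1.02 and -0.62 in deltaRE_whole). Of the 28 blocks within III, 13 interactions were called for deltaRE_right and 10 for deltaRE_whole (7 and 6 of them in every alternative run), and none of the 4 control blocks.

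For pairs of bins, limma called 0 between the mating types in deltaRE_right and 0 in deltaRE_whole, with 323 and 189 at an unadjusted p under 0.05. The counts became 13 without MATalpha deltaRE_right replicate 3 and 1 without MATalpha deltaRE_whole replicate 1, and 8 and 53 with library weights.

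**Figure D3:**
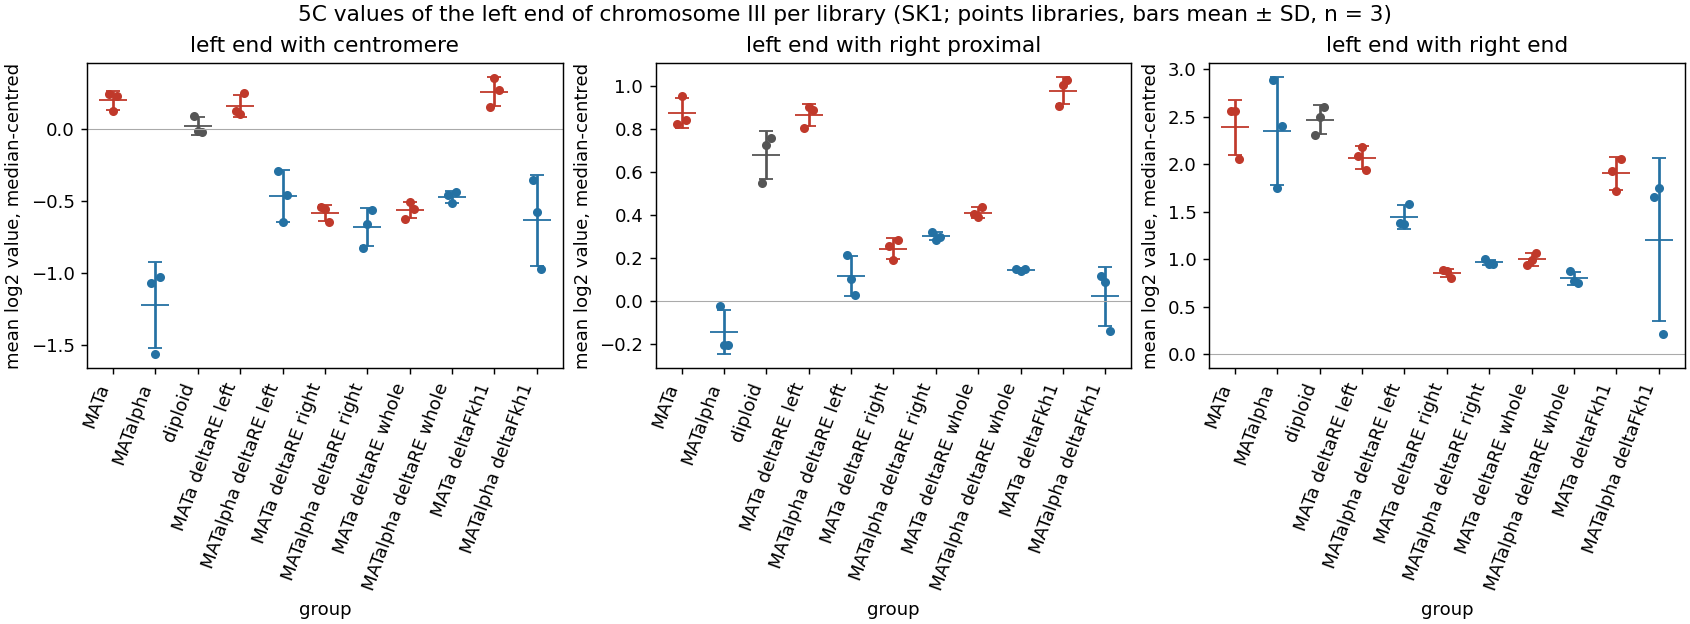
Log2 values per 5C library (points) with mean and SD (n = 3) for left end with the centromere part, the right proximal part and the right end of III, in the 11 SK1 groups. For the centromere part the mean is 0.20 in MATa and -1.22 in MATalpha, and -0.58 and -0.68 in deltaRE_right.

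In deltaRE_left cells the mating types still differed. Left end with the right proximal part was 0.87 ± 0.05 in MATa and 0.12 ± 0.09 in MATalpha (n = 3 each; rise 0.75, SE 0.0669, adjusted p 7.25e-10), and with the centromere part 0.16 ± 0.08 against -0.46 ± 0.18 (rise 0.63, SE 0.123, adjusted p 0.000331). Left middle rose with the right proximal part by 0.49 (adjusted p 1.09e-05) and with the MAT part by 0.48 (adjusted p 0.000362), and 6 blocks within III were called, all higher in MATa. Of these, 4 kept their call in every alternative run. Right proximal with right end (0.27) was not called without MATalpha deltaRE_left replicates 2 (0.24) or 3 (0.08) or MATa deltaRE_left replicates 1 (0.25) or 3 (0.24), and left end with right distal (0.44) not without MATalpha deltaRE_left replicates 1 (0.34) or 2 (0.42) or MATa deltaRE_left replicates 1 (0.44) or 3 (0.41). The difference at left end with the centromere part was smaller than in wild type by 0.80 (interaction -0.80, SE 0.174, adjusted p 0.00185), and that at left end with the right proximal part did not differ by the test (interaction -0.27, SE 0.0947, adjusted p 0.082). In pairs of bins 127 were called, 14 within III (4.61% of those tested) and 42 within V and XII (1.17% and 1.54%). That count was 191 without MATalpha deltaRE_left replicate 1, 55 without MATa deltaRE_left replicate 1, and 0 when only the 2 groups were fitted.

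In deltaFkh1 cells the left end also differed between mating types. There the left end with the right proximal part was at 0.98 ± 0.06 in MATa and 0.02 ± 0.14 in MATalpha (n = 3 each; rise 0.96, SE 0.0669, adjusted p 3.05e-12), with the centromere part 0.26 ± 0.10 against -0.63 ± 0.32 (rise 0.90, SE 0.123, adjusted p 1.81e-06), and with the MAT part it rose by 0.66 (SE 0.120, adjusted p 8.94e-05). Within III, 14 blocks were called, all higher in MATa, and 4 of them kept their call in every alternative run: left end with the centromere, right proximal and MAT parts, and right proximal with right end. Of the other 10, left middle with itself (0.23) turned to -0.02 without pairs under 30 kb, and centromere with right end (0.35, overlapping libraries) was not called in 11 of 14 alternatives and was 0.15 without MATalpha deltaFkh1 replicate 3. Left end with the right end (0.70, overlapping libraries) was not called without MATalpha deltaFkh1 replicate 3 (0.20) or MATa deltaFkh1 replicate 1 (0.68) or 3 (0.62), with library weights (0.50), without the RE bin (0.75) or when only the 2 groups were fitted (0.67). Of the interactions with deltaFkh1, limma called left end with the left middle (-0.48, SE 0.0829, adjusted p 0.000177), where the mating types in deltaFkh1 were 0.16 ± 0.05 and 0.09 ± 0.08. The interaction at left end with the centromere part was -0.53 and was not called. In pairs of bins 6 were called, all higher in MATa and 5 within III, with 19, 10 and 3 without MATalpha deltaFkh1 replicates 1, 2 and 3, and 0 when only the 2 groups were fitted.

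Each deletion was also compared with wild type of the same mating type, to see which side moved. In MATa, deltaRE_right lowered contacts of the left end with the centromere part by 0.78 (difference -0.78, SE 0.123, adjusted p 1.22e-05), with the right proximal part (-0.63, SE 0.0669, adjusted p 2.88e-08) and with the MAT part (-0.68, SE 0.120, adjusted p 4.27e-05). In MATalpha, deltaRE_right raised left end with the centromere part by 0.54 (SE 0.123, adjusted p 0.00067), the right proximal part by 0.45 (SE 0.0669, adjusted p 3.44e-06) and the left middle by 0.53 (SE 0.0586, adjusted p 2.21e-08). In deltaRE_whole the changes with the centromere part were -0.76 in MATa (adjusted p 1.81e-05) and 0.75 in MATalpha (adjusted p 1.28e-05). The deletion libraries have narrower log2 values, and dividing each library by its SD over pairs within V and XII, a test added later, moved these unevenly. The MATalpha rises became 0.30 in deltaRE_right and 0.48 in deltaRE_whole and the MATa falls -0.87 and -0.84, all still called.

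Contacts between the left and right ends of III fell in deltaRE_right and deltaRE_whole cells of either mating type. Left end with right end was 0.86 ± 0.04 in MATa deltaRE_right against 2.39 ± 0.29 in MATa (difference -1.53, SE 0.255, adjusted p 2.32e-05), and 0.97 ± 0.03 in MATalpha deltaRE_right against 2.35 ± 0.57 in MATalpha (difference -1.38, adjusted p 7.17e-05). In deltaRE_whole it fell by 1.39 in MATa (1.00 ± 0.06, adjusted p 7.72e-05) and by 1.55 in MATalpha (0.80 ± 0.07, adjusted p 1.28e-05; -1.03 after dividing by the SD). Contact of the left end with the right distal part fell by 1.12 and 1.02 in deltaRE_right and by 0.97 and 0.98 in deltaRE_whole (MATa and MATalpha), and the MATalpha falls were -0.61 and -0.59 when only the groups compared were fitted. With the telomere regions of V and XII the left end changed by -0.55 and -1.34 in deltaRE_right and -0.38 and -1.30 in deltaRE_whole (MATa and MATalpha), all called. The MATa deltaRE_whole call was lost in some alternative runs, and overlap of libraries is not stated for these 4 blocks. They were not divided by the SD of each library. RE with HMR fell by 2.95 in MATa deltaRE_right (4.15 ± 0.38 to 1.19 ± 0.24, SE 0.401, adjusted p 0.000141) and fell by 3.17 in MATa deltaRE_whole (SE 0.401, adjusted p 3.95e-05). The RE bin holds 1 probe fragment, and how far the deletions reach into it is not given in the labels. HML with HMR was called in none of the 4 comparisons, with -1.20 and -0.78 in deltaRE_right and -1.26 and -0.97 in deltaRE_whole (MATa and MATalpha; adjusted over the list alone, p 0.140 to 0.407). Bins 1 to 10000 and 270001 to 280000, which do not hold RE, fell by 2.27 in MATa deltaRE_right (SE 0.278, adjusted p 4.59e-05). Bins 250001 to 260000 and 260001 to 270000 rose by 1.54 in MATa and 1.40 in MATalpha deltaRE_right (limma adjusted p 3.53e-05 and 4.07e-05). They rose by 1.45 in MATa deltaRE_whole (adjusted p 3.95e-05).

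These comparisons with wild type also called blocks and many pairs away from III. The control block of the left telomere region of V with the rest of V changed by -0.27 in MATa deltaRE_right, -0.41 in MATalpha deltaRE_right, -0.26 in MATa deltaRE_whole and -0.31 in MATalpha deltaRE_whole. The first of these was not called without MATa deltaRE_right replicate 2 (-0.18), and the others were called in every alternative run. The same block of XII changed by 0.19 in MATalpha deltaRE_whole, not called without MATalpha replicates 2 (0.16) or 3 (0.16) or when only the 2 groups were fitted (0.20). MATa deltaRE_right had 666 called pairs, 47 within III and 321 of 2971 within V and XII, and MATalpha deltaRE_right 519, with 48 and 265. MATa deltaRE_whole had 708 (40 and 347) and MATalpha deltaRE_whole 532 (52 and 245). As shares of the tested pairs, calls in MATa deltaRE_right took 15.5% within III, 12.1% within V and 10.1% within XII. In MATalpha deltaRE_right they took 15.8%, 10.5% and 8.06%, and in MATa deltaRE_whole 13.2%, 13.4% and 10.8%. In MATalpha deltaRE_whole they took 17.1%, 8.50% and 8.12%. The SD of log2 values within V and XII was 0.596 to 0.725 in the deltaRE_right and deltaRE_whole libraries and 0.810 to 0.980 in the wild-type haploids. Without a library the counts fell by more than 1.5 times in MATa deltaRE_right (338 and 440 without MATa replicates 1 and 3, and 284, 287 and 275 without its own replicates 1, 2 and 3) and MATa deltaRE_whole (397 without MATa replicate 1, and 356, 328 and 386 without its own). The same held for MATalpha deltaRE_right (296 without MATalpha replicate 1, and 324, 286 and 334 without its own) and MATalpha deltaRE_whole (340 without MATalpha replicate 1, and 267, 350 and 229 without its own). With only the groups compared in the fit, the 2 MATalpha counts were 0 and 9.

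In MATa deltaRE_left, contact of the left end of III was not called as changed with the parts that fell in deltaRE_right: 0.16 ± 0.08 with the centromere part (difference -0.04, SE 0.123, adjusted p 0.859) and 0.87 ± 0.05 with the right proximal part (difference -0.01, SE 0.0669, adjusted p 0.936). Contact of the left end with the left middle fell by 0.22 (SE 0.0586, adjusted p 0.0104), but was not called without MATa replicate 1 (-0.20) or 3 (-0.20). Bins 1 to 10000 and 40001 to 50000 fell by 1.01 (1.22 ± 0.12 to 0.21 ± 0.35, SE 0.171, adjusted p 0.00372; not called when only the 2 groups were fitted). RE with HMR was 2.86 ± 0.46 against 4.15 ± 0.38, a difference of -1.28 (SE 0.401) called when adjusted over the list alone (list p 0.0298) and not over all pairs (adjusted p 0.0750). In MATalpha, deltaRE_left raised left end with the centromere part by 0.76 (SE 0.123, adjusted p 2.95e-05) and lowered left end with the right end (-0.90, SE 0.255, adjusted p 0.00567) and with the telomere regions of V and XII (-1.16, SE 0.143, adjusted p 5.1e-07). The control block of the left telomere region of V fell by 0.20 in MATalpha deltaRE_left (overlapping libraries), not called without MATalpha replicate 2 (-0.17), MATalpha deltaRE_left replicates 1 (-0.10) or 2 (-0.22), with library weights (-0.19) or when only the 2 groups were fitted (-0.24). MAT with HMR was 1.79 ± 0.09 in MATalpha deltaRE_left and -0.28 ± 0.65 in MATalpha (rise 2.06, SE 0.294, adjusted p 0.000159; not called when only the 2 groups were fitted). Called pairs of bins numbered 269 in MATa (4 within III, 100 within V and XII) and 990 in MATalpha (46 and 338), and 0 in both when only the groups compared were fitted. As shares of the tested pairs within III, V and XII these were 1.32%, 2.73% and 3.70% in MATa. In MATalpha they were 15.1%, 12.6% and 10.7%. The count of 269 became 119 and 148 without MATa replicates 1 and 3 and 82 without MATa deltaRE_left replicate 1. Bins 100001 to 110000 and 190001 to 200000 rose by 1.97 in MATa and 2.09 in MATalpha deltaRE_left (limma adjusted p 0.012 and 0.00219).

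MATa deltaFkh1 differed from MATa in 0 of 37 blocks (limma), and left end with the centromere part was 0.26 ± 0.10 (difference 0.06, SE 0.123, adjusted p 0.852). In pairs of bins 22 were called, 0 within III, with 977 at an unadjusted p under 0.05; the count was 2 and 5 without MATa replicates 1 and 3, 53 without MATa replicate 2, and 9 and 5 without MATa deltaFkh1 replicates 2 and 3. In MATalpha, deltaFkh1 raised left end with the left middle by 0.53 (SE 0.0586, adjusted p 5.34e-08) and left end with the centromere part by 0.59 (SE 0.123, adjusted p 0.00044; not called when only the 2 groups were fitted). Left end with right end was 1.21 ± 0.86 against 2.35 ± 0.57 (difference -1.14, SE 0.255, adjusted p 0.000718), with overlapping libraries, was -0.64 without MATalpha deltaFkh1 replicate 3, and was not called when only the 2 groups were fitted. The 33 called pairs of bins in MATalpha, 5 of them within III, became 63 and 102 without MATalpha replicates 2 and 3 and 12 without MATalpha deltaFkh1 replicate 3. The control block of XII rose by 0.15 in MATalpha deltaFkh1 (overlapping libraries) and lost its call without any 1 library except MATalpha replicate 1, down to 0.12, and when only the 2 groups were fitted. Both deltaFkh1 counts were 0 when only the groups compared were fitted. Every deletion raised the left end with the left middle over the same MATalpha libraries, by 0.26, 0.53, 0.60 and 0.53. With the centromere part the rises were 0.76, 0.54, 0.75 and 0.59 (deltaRE_left, deltaRE_right, deltaRE_whole and deltaFkh1). These comparisons alone cannot part an effect of each deletion from a trait of the shared MATalpha libraries.

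The parts of RE were set against each other in MATa. Compared with deltaRE_left, deltaRE_right had less contact of the left end with the centromere part (difference -0.74, SE 0.123, adjusted p 2.06e-05), the right proximal part (-0.62, SE 0.0669, adjusted p 1.84e-08), the right distal part (-1.36, SE 0.135, adjusted p 6.61e-09) and the right end (0.86 ± 0.04 against 2.07 ± 0.12, -1.21, SE 0.255, adjusted p 0.000303). Within III 18 blocks were called, 15 of them lower in deltaRE_right, and 12 of the 18 kept their call in every alternative run. The control blocks of V (-0.24) and XII (0.16) were called too, but not without MATa deltaRE_right replicate 2 (-0.15 and 0.15), and that of XII not without MATa deltaRE_left replicate 1 (0.14). Right proximal with right distal (-0.42) turned to 0.05 when only these groups were fitted. The largest named negative differences of single pairs lay outside the left end. They were bins 40001 to 50000 with 100001 to 110000 (difference -2.44, SE 0.295, limma adjusted p 4.94e-05) and 100001 to 110000 with 190001 to 200000 (-2.31, SE 0.409, adjusted p 0.00285). Their calls in the alternatives are not listed here. The first of them was -0.66 in deltaRE_right, 1.78 in deltaRE_left and 1.35 in wild-type MATa. The second was -1.72, 0.60 and -1.37, so it mostly reflects the rise in deltaRE_left. Bins 1 to 10000 and 250001 to 260000 were lower by 2.13 (difference -2.13, SE 0.240, adjusted p 2.53e-05; not called when only these groups were fitted). Of 258 called pairs of bins, 36 were within III (11.8% of those tested) and 126 within V and XII (4.79% and 3.95%). The count was 146 without MATa deltaRE_left replicate 1, 66, 84 and 57 without MATa deltaRE_right replicates 1, 2 and 3, and 2 when only these groups were fitted.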

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

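The use of Hi-C to check the rise in MATa, the tests of contrasts free of bin factors, the test on narrower log2 values and the dealing of residuals among libraries were chosen only after the result was seen.

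The mating types differed in another way in a deletion strain than in wild type, tested as an interaction in limma (SK1 5C, 3 libraries in each of 4 groups). For deltaRE_right the interactions at the left end of III were -0.51 with the left middle, -1.32 with the centromere part, -1.08 with the right proximal part, -0.86 with the MAT part, 0.79 with the telomere regions of V and XII and -0.62 with CEN5 and CEN12. At the right end they were -0.81 with the centromere part and -0.60 with the right proximal part, and right proximal with MAT gave -0.26. These kept their call in every alternative run, apart from the telomere regions (0.49, not called, without the RE bin). The other interactions called for deltaRE_right each lost their call without at least 1 library. Left middle with itself (-0.34) lost it without MATalpha replicate 1 (-0.07), MATa replicate 1 (-0.31) or MATalpha deltaRE_right replicate 2 (-0.32). Left middle with the right proximal part (-0.31) lost it without MATalpha replicate 3 (-0.26) or MATa replicate 1 (-0.27), and centromere with MAT (-0.40) without MATalpha deltaRE_right replicate 2 (-0.33). For left middle with MAT (-0.41) the libraries were MATalpha replicate 2 (-0.32), MATalpha deltaRE_right replicate 2 (-0.30) and MATa deltaRE_right replicate 1 (-0.36). For left middle with the centromere part (-0.37) they were MATalpha replicates 2 (-0.29) and 3 (-0.32), MATa replicate 1 (-0.32), MATalpha deltaRE_right replicate 3 (-0.32) and MATa deltaRE_right replicates 1 (-0.37) and 3 (-0.34). For MAT with itself (0.34) they were MATalpha replicate 1 (0.23), MATa replicate 2 (0.29), MATalpha deltaRE_right replicate 2 (0.18) and MATa deltaRE_right replicates 1 (0.35) and 2 (0.31). MAT with itself also lost it without pairs under 30 kb (0.18), with the looser filter (0.24), without centring (0.26), with library weights (0.30) and with only the groups compared (0.32). Left middle with itself lost it with the looser filter (-0.33) and without pairs under 30 kb (-0.71), and left middle with the centromere part (-0.38) and with MAT (-0.42) with only the groups compared.

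For deltaRE_whole the interactions at the left end were -0.58 with the left middle, -1.52 with the centromere part, -0.75 with the right proximal part, 0.91 with the telomere regions of V and XII and -0.40 with CEN5 and CEN12. Left middle with the centromere part gave -0.46, and the right end gave -1.02 with the centromere part and -0.62 with the right proximal part. These kept their call in every alternative run, apart from CEN5 and CEN12 (-0.31, not called, without the RE bin). Left end with MAT (-0.48) was not called without MATalpha replicates 2 (-0.46) or 3 (-0.40), MATa replicate 3 (-0.43), MATalpha deltaRE_whole replicates 1 (-0.45) or 2 (-0.46), or MATa deltaRE_whole replicate 3 (-0.45). Right proximal with MAT (-0.25) was not called without MATalpha deltaRE_whole replicate 1 (-0.23) or MATa deltaRE_whole replicate 3 (-0.24). Left middle with the right end (-0.58) lost its call without any 1 library except MATalpha replicate 1, MATa replicate 3 and MATa deltaRE_whole replicate 2, down to -0.41 without MATalpha replicate 2. Centromere with MAT (-0.32) lost it without any 1 library except MATalpha replicate 1, MATa replicate 3, MATalpha deltaRE_whole replicate 2 and MATa deltaRE_whole replicate 2, down to -0.26 without MATa replicate 1. III with XII (0.22) lost it without MATalpha replicates 2 (0.23) or 3 (0.18), MATa replicate 3 (0.20), MATalpha deltaRE_whole replicates 1 (0.23) or 2 (0.19), or MATa deltaRE_whole replicates 1 (0.22) or 3 (0.21), and was 0.15 without centring and 0.05 centred per distance, not called in either. After dividing each library by its SD over pairs within V and XII, left end with MAT was -0.41 and not called. With only the groups compared, left middle with the right end (-0.67) and centromere with MAT (-0.33) were not called.

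For deltaRE_left the interactions were -0.48 at left end with the left middle and -0.80 with the centromere part, both called in every alternative run, and 0.78 with the telomere regions of V and XII, not called without MATa replicate 1 (0.65) or without the RE bin (0.80). For deltaFkh1 the interaction was -0.48 at left end with the left middle, called in every alternative run. At this block deltaRE_right (-0.51) and deltaRE_whole (-0.58) gave much the same. All of these interactions use the same wild-type libraries, so a trait of those libraries cannot be told apart from effects of the deletions there. In pairs of bins the interactions called by limma numbered 7 for deltaRE_left, 2 for deltaRE_right, 4 for deltaRE_whole and 0 for deltaFkh1, against 982, 639, 618 and 704 at an unadjusted p under 0.05. Without a library these counts ranged from 2 to 26, 0 to 8, 0 to 14 and 0 to 7. Of 100 drawn divisions of the 12 libraries, 34, 7, 7 and 100 gave as many called pairs as the real division, with highest counts of 466, 168, 98 and 41 in the others. These divisions mix genotypes, a structure of the samples, so they decide nothing on the interactions, and with 0 calls the 100 for deltaFkh1 was fixed beforehand. With the effects of mating type and deletion kept and only the residuals dealt anew among the 12 libraries, 18, 2 and 1 of 100 dealings gave as many for deltaRE_left, deltaRE_right and deltaRE_whole (highest other 42, 2 and 2). Chance is thus not excluded for deltaRE_left. For the other 2 it is excluded only if residuals can be exchanged between libraries, which the narrower values of the deletion libraries put in doubt.

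The rise of the left end of III with the centromere part in MATa over MATalpha was weighed against technical explanations. The left end bins fell with V and XII outside the centromere and telomere regions (mean -0.25, SE 0.0496, 131 pairs), but this says nothing on their brightness, since balancing removes a factor of a bin. A contrast in which factors shared by the bins of a part drop out, the block minus the mean of both parts with themselves, differed by 1.51 (SE over libraries 0.129) for the centromere part and 1.09 (SE 0.0936) for the right proximal part, with all 3 MATa libraries higher, so such factors are not the cause. The sparse library MATalpha replicate 1 was not the cause, since the difference without it was 1.498 (SE 0.134, adjusted p 8.45e-10, all 3 MATa libraries higher; adjusted p at most 0.000179 over all alternatives of this block). Hi-C, read by another method, gave 1.34 (SE 0.0439, 2 MATa libraries above 2 MATalpha libraries). The difference thus repeated in separate libraries. A difference in conformation that goes with mating type may explain the rise. Hi-C repeats the same contrast, so it cannot part mating type from any other difference between these strains.

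The many called pairs within V and XII in deltaRE_right against wild type were weighed next. A difference in the spread of log2 values is not their whole cause. After each library was divided by its SD there, 96.2% as many pairs were called (318 in place of 321 in MATa and 246 in place of 265 in MATalpha, of 2971). The differences in MATa and in MATalpha, computed from different libraries, correlated across these pairs (Pearson r 0.664, Spearman 0.643, 2971 pairs that are not independent). A batch shared by the deletion libraries and an effect of the deletion both predict this correlation and cannot be told apart, since the labels give no batch.

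The fall of left end with right end of III in deltaRE_right and deltaRE_whole was weighed against what the deletion does to its own bin. Without the RE bin the mean change over the 4 comparisons was -1.24 (SE over libraries 0.233, with the shared wild-type libraries counted once), against -1.46 with it, and all 4 were called (adjusted p 0.000496 to 0.00344). That the RE bin changed by 0.0058 with V and XII (SE 0.0607, 43 pairs) says nothing on a dimmer fragment, since balancing removes it. A contrast in which factors of the RE bin, the right end and V and XII drop out was -2.14 (SE over libraries 0.161). A factor common to all pairs of the RE bin therefore does not account for the fall in that bin. A fragment shortened or lost, with its signal down to background, would not act as such a factor, so the contrast cannot decide on that case. Narrower log2 values in these libraries are not the whole cause, since the mean after scaling was -0.99 (SE over libraries 0.142; -1.08, -0.93, -0.93 and -1.03). The same 6 wild-type libraries serve in these comparisons, so a batch shared by the deletion libraries stays open. The left end also fell with the telomere regions of V and XII. The changes were -0.55 in MATa and -1.34 in MATalpha for deltaRE_right, and -0.38 and -1.30 for deltaRE_whole. These blocks were not divided by the SD of each library. How far narrower log2 values account for these changes was thus not tested, and no reach of the fall beyond III is concluded. A role of RE in holding the ends of III together may explain the fall with the right end only as a hypothesis, which was not tested.

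The 6 libraries of a comparison make 10 splits, and 10 splits cannot give a share under 0.05. The real split gave the most called pairs (1 of 10 as large) in MATa against MATalpha (40, highest other 3), diploid against MATalpha (12, other 11), and each deletion against wild type: deltaRE_left 269 and 990 (others 9 and 36), deltaRE_right 666 and 519 (0 and 2), deltaRE_whole 708 and 532 (0 and 4) and deltaFkh1 22 and 33 (3 and 16), MATa and MATalpha in turn. It did so too between the mating types in deltaRE_left (127, other 42) and deltaFkh1 (6, other 2), and for deltaRE_right against deltaRE_left (258, other 0). For diploid against MATa the real split gave 1 and 6 of 10 were as large, the highest 13 with MATa replicates 1 and 3 and diploid replicate 3 against the rest. Between the mating types limma called 0 in deltaRE_right (highest other 1), deltaRE_whole (0) and W303 (0), so 10 of 10 splits were as large, with 323, 189 and 536 pairs at an unadjusted p under 0.05.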

How the results depend on the processing

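The fits with library weights and without the RE bin were chosen only after the data were seen; no alternative chosen beforehand was left unrun. Blocks held better than pairs of bins. Of the called blocks other than control blocks, 1690 of 1880 block and alternative combinations kept direction and call, 186 lost the call and 4 reversed; leaving out 1 library, 1369 of 1612 kept both. For the named pairs of bins 459 of 554 did, and 354 of 468 on leaving out 1 library. In MATa against MATalpha (SK1 5C), left end with the centromere part ranged from 1.25 to 1.52 over 14 alternatives (highest adjusted p 0.000179), with the right proximal part from 0.979 to 1.08, with MAT from 0.562 to 0.754, with the left middle from 0.519 to 0.703 and with the telomere regions of V and XII from -0.830 to -0.618, all called in each.

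Fitting only the groups compared changes both the samples behind the spread and the pairs tested, since a pair enters when all libraries of the fit have a value; which of these acted was not tested. It ended 64 of 222 block calls and 62 of 72 calls of named pairs. Its counts of called pairs were 0 in MATa against MATalpha, diploid against MATa, diploid against MATalpha, MATa and MATalpha deltaRE_left, MATalpha deltaRE_right, MATa and MATalpha deltaFkh1 (each against wild type), between the mating types in deltaRE_left and deltaFkh1, and in the interactions of deltaRE_left, deltaRE_right and deltaRE_whole. It was 9 in MATalpha deltaRE_whole and 2 in deltaRE_right against deltaRE_left.

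For the other alternatives, too, the cause was not tested. With library weights the counts were 18 in MATa against MATalpha, 0 in diploid against MATa, 153 and 221 in MATa and MATalpha deltaRE_left, 1419 in MATa deltaRE_right, 1563 in MATa deltaRE_whole, 17 in MATalpha deltaFkh1, and 842 in deltaRE_right against deltaRE_left. Between the mating types they were 14 in deltaRE_left, 8 in deltaRE_right, 53 in deltaRE_whole and 13 in deltaFkh1, and in the interactions 1, 11, 19 and 2, in that order. Weights ended 13 of 222 block calls, leaving out the RE bin 20, the looser filter (finite in at least 2 libraries of each group) 34, no centring 20 and leaving out pairs under 30 kb 10 of 216. Centring per distance ended 20 of 244 and the replicate block 4 of 244.

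With the looser filter, diploid against MATa gave 3 pairs, MATa deltaRE_left 404, and the interactions of deltaRE_left and deltaRE_whole 3 and 1. Without centring, MATalpha deltaFkh1 gave 53 and the interactions of deltaRE_left, deltaRE_whole and deltaFkh1 4, 7 and 1. Centred per distance, MATalpha deltaFkh1 gave 52 and the interactions of deltaRE_right, deltaRE_whole and deltaFkh1 4, 8 and 1. The deltaRE_whole interaction gave 1 with the replicate block and 1 without the RE bin. Centring moved the share of higher calls in MATa deltaFkh1 (17 of 22 higher; 11 of 18 without centring, 19 of 30 per distance), MATalpha deltaFkh1 (20 of 33; 40 of 53 without), the mating types in deltaFkh1 (6 of 6; 5 of 6 per distance) and the deltaRE_left interaction (6 of 7; 4 of 4 without). In MATa against MATalpha, means over 3 by 3 bins gave 5 landmark pairs when adjusted over the list of 10 alone, against 3 of 8 for single pairs of bins. Of the 5, RE with CEN3 and RE with MAT could not be tested as single pairs. The difference in decay slope on III was 0.563 at 30 to 150 kb.

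Without 1 library the counts ranged from 20 to 61 in MATa against MATalpha, 0 to 11 in diploid against MATa and 13 to 34 against MATalpha. Against wild type (MATa, then MATalpha) they were 82 to 316 and 731 to 949 for deltaRE_left, 275 to 531 and 286 to 663 for deltaRE_right, 328 to 552 and 229 to 626 for deltaRE_whole, and 2 to 53 and 12 to 102 for deltaFkh1. Between the mating types they were 55 to 191 in deltaRE_left, 0 to 13 in deltaRE_right, 0 to 1 in deltaRE_whole and 3 to 19 in deltaFkh1, and in the interactions 2 to 26, 0 to 8, 0 to 14 and 0 to 7. DeltaRE_right against deltaRE_left gave 57 to 302, the called blocks in MATa against MATalpha 15 to 21, and limma called 0 pairs in W303, in Hi-C and among the landmark pairs of MATa against MATalpha (SK1 5C) in each of these fits (536 and 3177 pairs of W303 and Hi-C at an unadjusted p under 0.05 with all libraries).

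Some differences reversed; each is given with its value in the reported fit first. In MATa against MATalpha, CEN3 with MAT (-0.08) was 0.0785 without MATa replicate 1 (-0.197 to 0.0785 over the libraries left out), HML with HMR (0.33) -0.586 without MATalpha replicate 2 (to 0.886) and HML with RE (-0.35) 0.0177 without MATalpha replicate 1 (from -0.713). In Hi-C, HML with RE (0.06) was -0.00499 without MATalpha replicate 1 (to 0.137) and RE with MAT (0.07) -0.0737 without MATalpha replicate 2 (to 0.208). Left middle with itself (0.23) was -0.0293 in MATalpha deltaRE_left without MATalpha replicate 1 (to 0.278), and (0.23) -0.0162 between the mating types in deltaFkh1 without pairs under 30 kb. Right proximal with right distal (-0.42) was 0.0455 in deltaRE_right against deltaRE_left with only these groups fitted, and (-0.41) 0.00605 in MATalpha deltaRE_right with the looser filter. III with XII between the mating types in deltaFkh1 (-0.14) was 0.000469 centred per distance.

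In SK1 5C the replicate numbers were not taken to pair the libraries, since 5 of 165 pairs of libraries with the same number correlated above 0.1 (highest 0.223). Yet 23 of 33 libraries correlated best with a library of their own number, so a small effect shared by a number is not excluded. In Hi-C the correlation was 0.0097. With 2 replicates per group both pairs of the same number give this value by construction, so it is 1 value. Depth cannot be judged from ratios or balanced signal; the share of missing pairs and of pairs at 0 is what the files show of it.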

Other observations

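The test of the mean of the 2 haploids was chosen only after the result was seen. In the diploid, left end of III with the centromere part was 0.02, against 0.20 in MATa and -1.22 in MATalpha. If both copies of III in a diploid kept the forms seen in the haploids, the value would lie near a mean of the 2 haploid forms. That mean was taken from the haploids' block means, each turned back from log2, and is -0.34 as a log2. A mean taken pair by pair would lie as high or higher, and was not computed. The diploid lay above the mean of -0.34 by 0.36 (SE 0.110). The excess over a mean taken pair by pair would be no larger. Whether an even mix of both haploid forms describes the diploid at this block is thus not settled. The left end with the right proximal part (0.23, SE 0.0591) and with MAT (0.32, SE 0.105) lay above the mean from block means too, and right proximal with right end by 0.13 (SE 0.0761). The strains differ in ploidy as well as in mating type, and this was not separated.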
